A study of Mus musculus with 2 samples.

How the data were processed

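Single-cell RNA was measured in whole dissociated testis of mice with a droplet 3′ kit, in 1 control library (Dot1L fl/+, Cre-negative) and 1 Dot1L cKO library (Dot1L fl/delta, Ddx4-Cre). The deposited matrices hold UMI counts per gene and barcode, made with Cell Ranger 7.0.0, per the file headers. Per the submitters' processing notes the genome build is mm10, and Seurat 4.1.0 was used. No deposited file holds a clustering or a cell annotation, so cell types were rebuilt from the counts and may differ from those of the study. Every deposited barcode had 500 or more UMIs (lowest 500). That does not exclude droplets that hold free RNA alone, since free RNA was estimated at more UMIs per cell than this minimum. The tables list 32285 genes, of which 32235 were found in the GENCODE vM21 annotation of GRCm38 (mm10) by Ensembl identifier, and 32158 had a transcript sequence. There are 38 symbols used by more than 1 gene, and all joins used the identifier.

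The design, the gene lists, the markers, the rule for named genes and the other settings to try were fixed before the data were examined. Cells were kept with 500 or more UMIs, 300 or more genes and at most 10% mitochondrial UMIs. In the control library 1510 barcodes were over the mitochondrial limit and 9 under the gene minimum, and in the cKO library 2150 and 1, leaving 15897 and 18451. Doublets were scored per library against simulated doublets, 2 per cell, and 256 control (1.61%) and 506 cKO cells (2.74%) were removed. The thresholds caught only 17.2% and 22.5% of the simulated doublets, so most doublets stayed in. Kept cells numbered 15641 and 17945.

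Counts of both libraries were normalised to 10000 UMIs per cell and log-transformed. The 2000 most variable genes, without Dot1l and the transition protein, protamine and testis histone lists, gave 30 principal components, a graph of 20 nearest neighbours and Leiden clusters at resolution 1.0, with no batch integration. A cluster was called X-like by the fixed markers of 13 cell types when 3 or more markers were above other clusters. These naming thresholds were set and adjusted after the clusters were seen. A cluster whose best markers were somatic stayed unnamed when spermatid markers in it were over 66.7% of their level in all cells. A cluster was held apart as low RNA when its median UMI count was under 1/3 of the mean of cells of that name and its own markers were under 1.5 times the pooled level. The second condition kept the mesenchymal-like cluster and elongating cluster 3 named. Low-RNA clusters held 18.1% of control and 18.7% of cKO cells, and unnamed clusters 32.7% and 36.6%. The unnamed clusters were cluster 0, led by hemoglobin genes, clusters 1 and 5, in which Sertoli cell markers such as Cst9 and Cst12 were among the leading genes, and cluster 21, led by Gsta3 and Bhmt. Low-RNA clusters were put into their classes as an alternative chosen after seeing the data.

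UMIs were summed per class and library for classes with 100 or more cells in each, and a gene was measured with 50 or more UMIs over both libraries. Somatic cells (macrophage-like, mesenchymal-like and Leydig-like) were pooled as a comparison. No test was made, because cells of 1 library are not replicates. Log2 ratios of CPM carry exact intervals, and medians of fixed lists are given with their percentile among 10000 random lists of the same size matched on mean expression, as a description of these 2 libraries. A count over 1.5-fold is a rule of size. The 18 lists cover DOT1L and its partners, transition proteins and protamines, testis histones, histone removal, spermatid transcription, RNA storage, acrosome, manchette, flagellum, synaptonemal complex, meiotic divisions, stem cells, X and Y multicopy genes, glycolysis, p53 targets, dissociation stress, steroid synthesis and Sertoli cells.

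Named genes were, among genes with 100 or more UMIs in the class and 20 or more CPM in the higher library, the 15 highest and 15 lowest log2 ratios in round spermatids, 10 and 10 in elongating spermatids and in mid to late spermatocytes, and 5 and 5 in the other classes. Predicted and clone symbols, mitochondrial and hemoglobin genes and the markers of the class were passed over, 7 higher and 14 lower in round spermatids. They were 5 and 14 in elongating spermatids, 5 and 10 in mid to late spermatocytes, 3 and 2 in early spermatocytes and 2 and 1 in spermatogonia. Up to 4 members of each list with the largest absolute log2 ratio, and Dot1l, Tnp1, Tnp2, Prm1 and Prm2, were named too. The text gives part of these genes, and the others are counted in the summaries. The shared part of a 3′ end is the percent of the 40-nucleotide words in the last 400 nucleotides of a gene's longest transcript that transcripts of another gene also hold, and 50% or more shared counts as mostly shared.

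Free RNA was estimated from the spermatid markers found in somatic cells, at 1541 UMIs per control and 1747 per cKO cell. Its share of UMIs was 5.07% and 6.38% in mid to late spermatocytes, 6.22% and 7.69% in round spermatids and 16.8% and 21.5% in elongating spermatids. The estimate per cell was over the median of 816 UMIs in unnamed cluster 0. For some genes and classes it was also over the observed UMIs. It is thus too high in places, and values that rest on it are uncertain. The alternatives were stricter filters of 1000 UMIs and 500 genes, every barcode, doublets kept, resolutions of 0.5 and 2.0, germ cells alone as the denominator, classes by marker score, the mean of each cell's own CPM, the same cluster weights in both libraries, median-of-ratios scaling, totals without the 50 most abundant genes, thinning to 2000 UMIs, subtraction of free RNA and minimums of 20 and 200 UMIs. Of cells classed by marker score, 2352 of 15641 control and 2402 of 17945 cKO cells had their top scores within 0.1 of each other. Alternatives chosen after seeing the data were the low-RNA one, spermatids matched to control stages, and subtraction of the somatic ratio.

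The steps were tested on simulated counts with 200 changed genes. Both simulated libraries were Poisson counts drawn from the pooled profile of a class, with the most abundant genes left unchanged. Variation among cells, stages or libraries and a shift in the most abundant genes were thus not simulated. In the simulated round spermatid comparison, run on 16135 genes, genes set 2-fold higher had a median log2 ratio of 0.98 and 96% lay in their interval. Genes set at 4-fold had 2.01 and 98%, those at 0.5-fold −1.02 and 97.9%, and those at 0.25-fold −2.02 and 93.6%. Of unchanged genes 1.55% passed 1.5-fold. Of 100 simulated lists of unchanged genes 3 fell outside the central 95%, and 20 of 20 lists of doubled genes lay above it. In the simulated spermatogonium comparison, run on 10057 genes, 10 of 100 unchanged lists fell outside, in the elongating spermatid one (11881 genes) 5, in the mid to late spermatocyte one (16840 genes) 4 and in the early spermatocyte one (9535 genes) 2. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scikit-image 0.26.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.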

Results

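The data were single-cell RNA profiles of whole dissociated mouse testis from 2 genotypes, with 1 library each. The control animals were Dot1L fl/+ without Cre, and the conditional knockout (cKO) animals were Dot1L fl/delta with Ddx4-Cre. Ddx4 is a germ cell gene, so the somatic cells of the cKO testis were not the target of the Cre. By the genotype labels, cKO somatic cells still carry 1 delta allele where control cells carry a wild-type one. DOT1L is the enzyme that methylates lysine 79 of histone H3. The labels give no number of animals per library. The control library held 17408 barcodes and 155487418 UMIs (unique molecular identifiers, each standing for a captured transcript), with a median of 2383.5 UMIs per barcode. The cKO library held 20601 barcodes and 156518838 UMIs, with a median of 2188. After filtering, 15641 control cells and 17945 cKO cells were kept. With 1 library per genotype every difference below is between 2 libraries and has no replicate check. The 95% intervals, exact Poisson for UMI sums and Clopper-Pearson for shares, cover counting error only. Intervals given for a median over genes are order-statistic intervals, which show the spread over those genes. Log2 ratios are cKO over control, computed on CPM, the UMIs summed over the cells of a class and scaled to the total of that class.

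The shares of germ cell classes addressed which stages of spermatogenesis were present in the cKO testis. The cKO library had a higher share of spermatogonium-like and early spermatocyte-like cells and a lower share of round and elongating spermatid-like cells than the control library. The share of mid to late spermatocyte-like cells (pachytene to secondary) was close in both. Spermatogonium-like cells made up 1.34% (1.16 to 1.53) of control cells and 2.21% (2.0 to 2.43) of cKO cells. Early spermatocyte-like cells made up 2.23% (2.01 to 2.48) and 3.59% (3.32 to 3.87). Mid to late spermatocyte-like cells were 11.3% (10.8 to 11.8) and 10.7% (10.3 to 11.2). Round spermatid-like cells were 11.0% (10.5 to 11.5) of control and 8.21% (7.82 to 8.63) of cKO cells, a log2 ratio of −0.42. Elongating spermatid-like cells were 22.5% (21.9 to 23.2) and 17.5% (17.0 to 18.1), a log2 ratio of −0.36. Among cells of these 5 germ cell classes alone, spermatogonium-like cells were 2.76% and 5.22%, early spermatocyte-like cells 4.61% and 8.49%, mid to late spermatocyte-like cells 23.4% and 25.4%, round spermatid-like cells 22.6% and 19.4%, and elongating spermatid-like cells 46.5% and 41.5%. On that denominator the mid to late spermatocyte-like share was higher in the cKO library, with a log2 ratio of 0.11 against −0.08 over all kept cells. When each cell took the class of its highest marker score, the log2 ratio of the round spermatid-like share was −0.14 and that of the spermatogonium-like share 0.30. Cells in low-RNA clusters and in clusters without a name made up 50.8% of control and 55.4% of cKO cells and belong to none of these classes. Somatic cells in named clusters were few: macrophage-like cells numbered 59 in the control and 179 in the cKO library, mesenchymal-like cells 48 and 162, and Leydig-like cells 16 and 84. Unnamed clusters 1 (1684 and 2677 cells) and 5 (365 and 998) each had 10 Sertoli cell markers above other clusters. Unnamed cluster 21 (122 and 345) had 8 Leydig cell markers above them. The naming thresholds were adjusted after the clusters were seen, so unnamed clusters may hold more somatic cells.

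**Figure D1:**
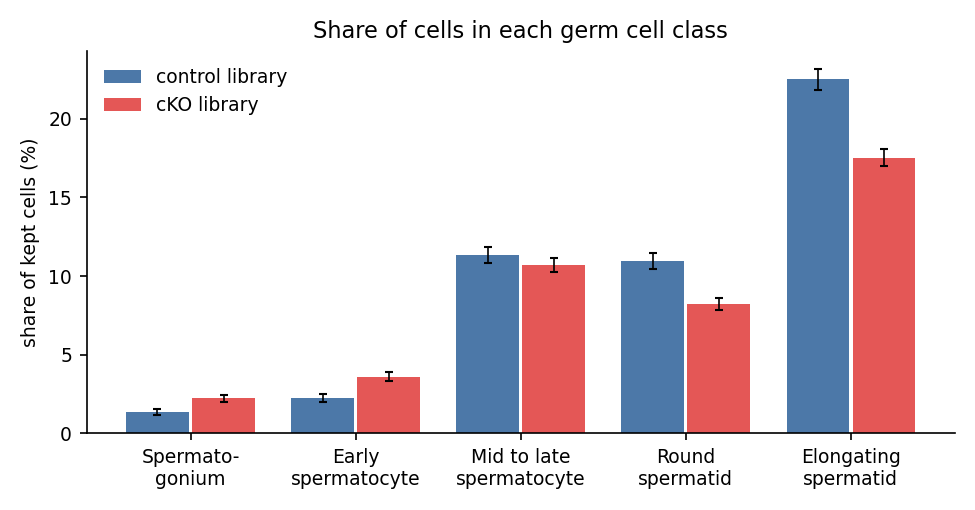
Share of kept cells in each germ cell class, in percent, for the control and the cKO library, with 95% Clopper-Pearson intervals. Round spermatid-like cells were 11.0% of control and 8.21% of cKO cells.

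Within the spermatid classes the libraries fell into different clusters. Control round spermatid-like cells lay mostly in cluster 20 (600 control and 1 cKO cells), cluster 23 (371 and 5) and cluster 10 (733 and 400). The cKO round spermatid-like cells lay mostly in cluster 18 (9 and 630), cluster 22 (1 and 438) and cluster 10. Control elongating spermatid-like cells were mostly in clusters 6 (1149 and 51), 12 (927 and 16) and 3 (1150 and 920). The cKO elongating spermatid-like cells were mostly in clusters 4 (18 and 1560), 3 and 14 (278 and 600). The 4 mid to late spermatocyte-like clusters, the 2 early spermatocyte-like clusters and the spermatogonium-like cluster held cells of both libraries. Genes reported for the class were among the 10 leading genes of some of these clusters. They were Phb in cluster 20, Hist2h2aa1 in cluster 23, Prm1 in cluster 6, and Prm1, Tnp1, Tnp2, H2al1a and H2al1g in cluster 12. Among clusters mostly of cKO cells, Tssk6 was a leading gene of cluster 4 and Ankrd9 of cluster 22. Both were named by size as higher in the cKO library in some class. A cluster mostly of 1 library may be that library and not a cell state.

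Cells of the cKO library had fewer UMIs in most classes, and at equal depth somewhat more genes. Elongating spermatid-like cells had a median of 7472 UMIs in the control and 6168 in the cKO library, and round spermatid-like cells 21185.5 and 19929.5. The median number of genes in elongating spermatid-like cells was 1516.5 and 1642. After thinning each cell to 2000 UMIs it was 684 and 813, with 302 control and 305 cKO cells left out as shallower. For round spermatid-like cells the medians were 4784 and 4893 genes, and 1258 and 1302 after thinning, with 2 and 3 cells left out.

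Dot1l, the targeted gene, was lower in the cKO library in the classes from spermatogonium-like to round spermatid-like cells, most in round spermatid-like cells. In these cells Dot1l (ENSMUSG00000061589, chromosome 10, 80755206 to 80795461, plus strand, mm10) had 1694 UMIs or 39.9 CPM in the control and 181 UMIs or 5.40 CPM in the cKO library, a log2 ratio of −2.88 (−3.11 to −2.66). The ratio was −0.81 (−1.20 to −0.43) in spermatogonium-like cells, −0.43 (−0.73 to −0.12) in early spermatocyte-like cells and −1.04 (−1.11 to −0.98) in mid to late spermatocyte-like cells. With the free RNA estimate subtracted it was −0.75, −0.28, −1.03 and −3.35 from spermatogonium-like to round spermatid-like cells. In elongating spermatid-like cells the ratio was −0.89 (−1.56 to −0.26) on 70 and 30 UMIs. The free RNA estimate for Dot1l there was 296 and 134 UMIs, more than was observed. The estimate is thus too high for these cells and cannot say how much of the ratio is free RNA. A difference in free RNA stays open. In somatic cells the Dot1l ratio was −0.91 (−1.78 to 0.01) on 17 and 37 UMIs, of which free RNA was estimated to supply 60.8% and 48.9%. With that somatic ratio subtracted, a setting chosen after the data were seen, the Dot1l ratio turned to 0.10 in spermatogonium-like, 0.49 in early spermatocyte-like and 0.02 in elongating spermatid-like cells, and was −0.13 in mid to late spermatocyte-like and −1.97 in round spermatid-like cells. That somatic ratio rests on 17 and 37 UMIs, and by the labels cKO somatic cells carry 1 delta allele. Subtracting it may thus remove an effect of genotype, so these values do not show that the germ cell difference is absent. The labels do not say which part of Dot1l is floxed, and a 3′ tag outside that part does not check the genotype label. Across the 4 mid to late spermatocyte-like clusters and round spermatid-like cluster 10, which hold both libraries and were put in order of falling Piwil1 after the values were seen, the Dot1l ratio was 0.03 in cluster 15, −0.80 in cluster 11, −1.92 in cluster 16, −2.81 in cluster 9 and −2.84 in cluster 10. Control Dot1l in them was 54.1, 104, 130, 106 and 67.1 CPM, and cKO Dot1l was 55.4, 59.7, 34.2, 15.1 and 9.36 CPM.

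**Figure D2:**
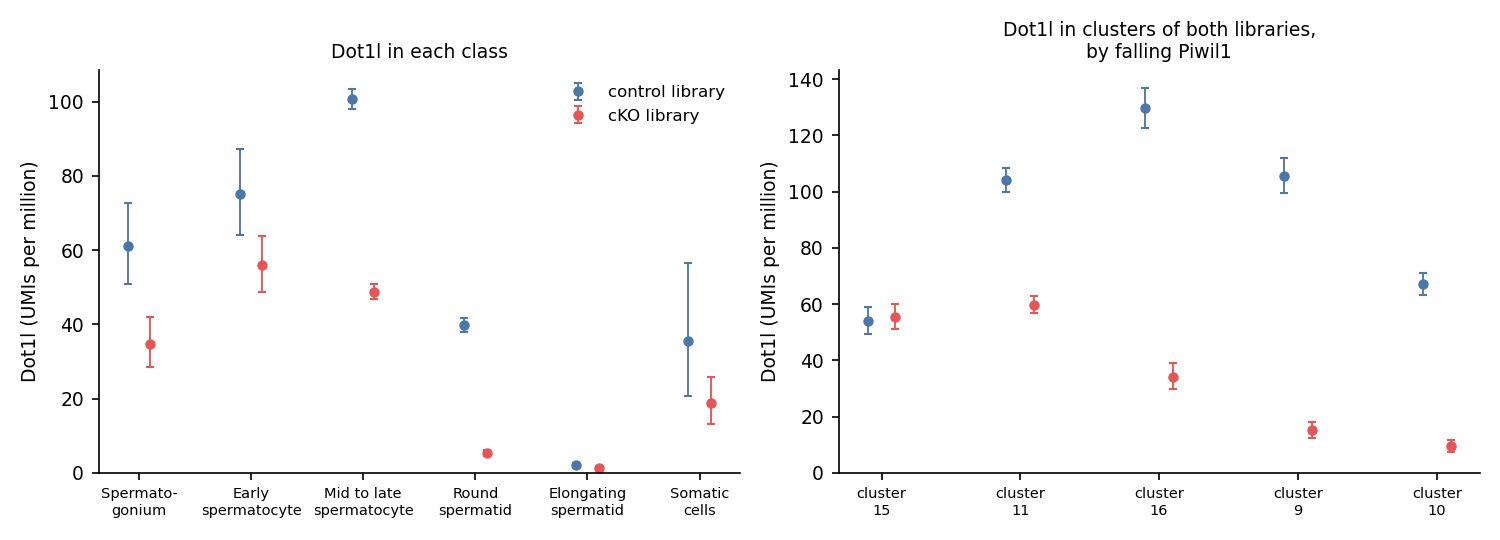
Dot1l level in CPM with exact Poisson 95% intervals in each germ cell class, in somatic cells and in the clusters ordered by Piwil1, for the control and the cKO library. In round spermatid-like cells the level was 39.9 CPM in the control and 5.40 CPM in the cKO library.

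Round spermatids are where histone replacement begins to be prepared, so transcripts of the transition proteins and protamines were the main gene group of interest in this class. These transcripts were lower in the cKO library in round spermatid-like cells. They were lower by a similar or larger log2 ratio in somatic cells, which should hold them only as free RNA. Most genes with the largest ratios that were measured in somatic cells differed there too. Lists of acrosome, flagellum and spermatid transcription genes were near the median of all genes. Over the 16134 genes measured in this class the median log2 ratio was 0.12. Medians of lists are to be read against that value and against their random lists, which for the acrosome ran from −0.11 to 0.13.

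The list of transition proteins, protamines and spermatid linker histones had a median of −0.63 in round spermatid-like cells, at percentile 0 among 10000 expression-matched random lists, with 5 of 7 genes over 1.5-fold lower. Prm1 (ENSMUSG00000022501, chromosome 16) had 10110 CPM in the control and 4559 CPM in the cKO library, a ratio of −1.15. The ratios of Tnp1, Tnp2, Prm2 and Prm3 were −0.91, −0.63, −0.60 and −0.67. In somatic cells Tnp1, Tnp2, Prm1 and Prm2 had ratios of −1.04, −0.97, −1.50 and −0.84. Over all kept cells they were −0.85, −0.59, −1.03 and −0.47. The somatic pools differed in cell mix, since RNA-rich Leydig-like cells were 16 of 123 control and 84 of 425 cKO cells. Spermatid markers were at 0.22 of their all-cell level in these cells, against 0.45 in macrophage-like and 0.59 in mesenchymal-like cells. No setting corrected for this mix. With the somatic ratio subtracted gene by gene, a setting chosen after the data were seen, the list median turned to 0.31. Tnp1, Tnp2, Prm1 and Prm2 together took 2.81% of round spermatid-like UMIs in the control and 1.59% in the cKO library.

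**Figure D3:**
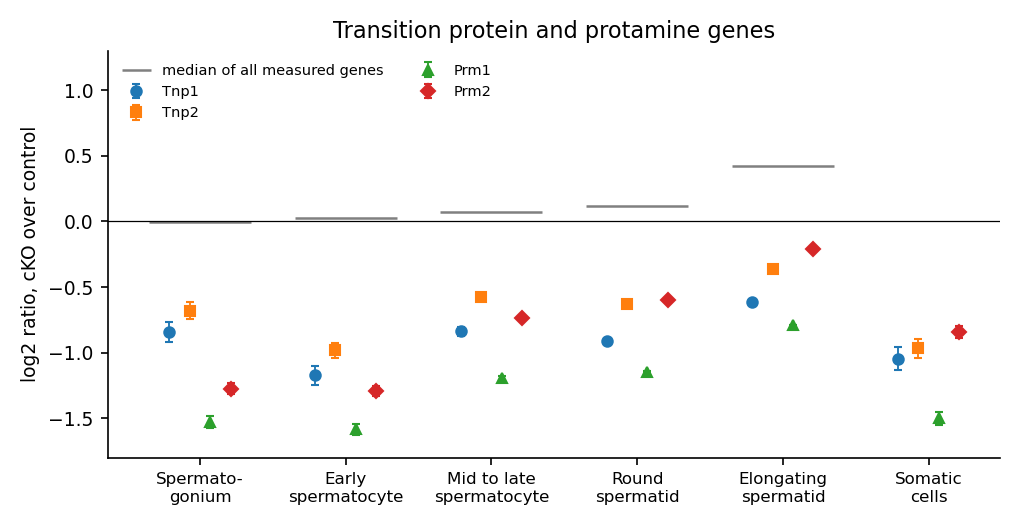
Log2 ratio of Tnp1, Tnp2, Prm1 and Prm2, cKO over control, in each germ cell class and in somatic cells, with exact 95% intervals and the median of all measured genes as a line. Prm1 was at −1.15 in round spermatid-like cells and at −1.50 in somatic cells.

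Of the other fixed lists in round spermatid-like cells, X and Y multicopy and Y-linked genes had a median of −0.16, at percentile 0.45. Zfy1 (−1.35) and Cypt2 (−0.78) were among its lowest, and the list's somatic median was −0.13. The other 16 lists lay inside the central 95% of random lists. Their medians were −0.01 for acrosome genes, −0.05 for the flagellum, −0.03 for glycolysis, 0.04 for testis histones, 0.06 for transcription regulators, 0.08 for RNA storage and 0.09 for meiotic divisions. They were 0.11 for the synaptonemal complex, 0.14 for the manchette, 0.17 for histone removal, 0.17 for Sertoli cell genes, 0.19 for spermatogonial stem cell genes and 0.26 for steroid synthesis. The list of DOT1L and its partners was at 0.29, p53 targets and apoptosis at 0.41 and dissociation stress genes at 0.48. Median-of-ratios scaling subtracts the class median of 0.12 from every gene alike, so the list medians between 0 and 0.12 lay below 0 under it: testis histones (−0.08), transcription regulators (−0.07), RNA storage (−0.04), meiotic divisions (−0.03) and the synaptonemal complex (−0.01). Single members differed by more. Zpbp (acrosome) had 1.37 with 2.23 in somatic cells, Smap2 (acrosome) 3.13 with 0.63, and Papolb (RNA storage) 1.08 with 0.75. Ddx4, whose promoter drives the Cre, had −0.68, with −0.41 in somatic cells. Gmcl1 was at 1.08, Bcorl1 at −1.58 on 209 and 55 UMIs, and Hist1h1t, the testis linker histone, at −1.21 on 580 and 198 UMIs. H2afx was at 0.63, with 2.24 in somatic cells. Hoxc9 (stem cell list) was at 2.87 on 40 and 230 UMIs, Gja1 (Sertoli list) at 1.54 with 0.13 in somatic cells, and Tex12 (synaptonemal list) at 1.54 with −1.20 in somatic cells. Among glycolysis genes Eno1, whose 3′ end is mostly shared, was at −1.27 and turned to 0.37 with the somatic ratio subtracted. Slc2a3 was at −0.47 and turned to 0.31 when clusters were given the same weights, which leaves cluster 10 alone.

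**Figure D4:**
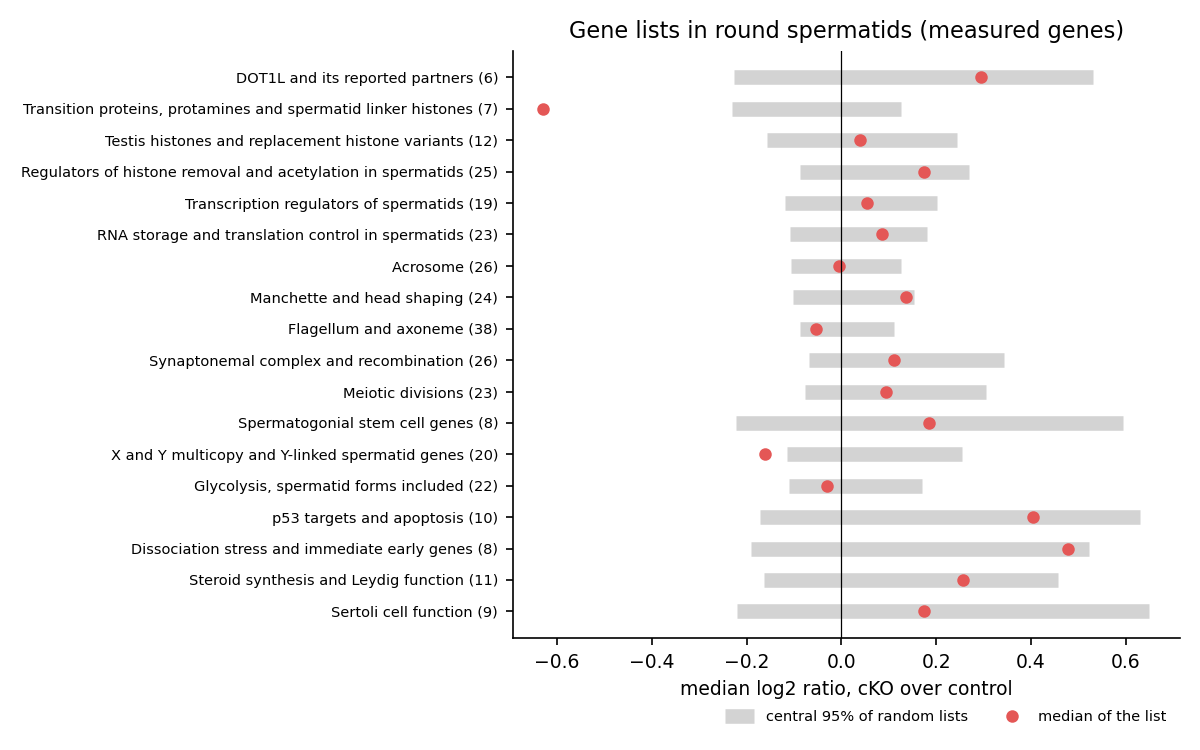
Median log2 ratio of each fixed gene list in round spermatid-like cells beside the central 95% of 10000 expression-matched random lists. The list of transition proteins, protamines and spermatid linker histones was at −0.63.

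Among round spermatid-like genes named by size, the highest included Scand1 (ENSMUSG00000046229, chromosome 2), Rabgef1 (ENSMUSG00000025340, chromosome 5) and Hal (ENSMUSG00000020017, chromosome 10). Scand1 had 546 control and 16478 cKO UMIs, a ratio of 5.26, and 5.41 in somatic cells. Rabgef1 was at 4.58, with 2.76 in somatic cells. Hal was at 4.05 on 124 and 1621 UMIs and was not measured in somatic cells. Of the 15 highest genes, 14 were measured in somatic cells, all 14 with the same sign and 13 over 1.5-fold. Their median was 3.26 in round spermatid-like and 2.43 in somatic cells. Of the 15 lowest, 5 were measured in somatic cells, all 5 with the same sign and 4 over 1.5-fold. Among the lowest, Bloc1s1 was at −2.75 in round spermatid-like and −2.71 in somatic cells. Phb (chromosome 11), with no shared 3′ end, was at −3.82 on 5434 and 304 UMIs and at −1.63 in somatic cells. Hist2h2aa1 had −6.00 on 8335 and 103 UMIs, and the X-linked genes H2al1a and H2al1g had −5.27 and −5.24. These 3 histone genes, Bloc1s1 and Dynlt1b (−2.90) share 90% or more of their 3′ ends with another gene, so their counts are uncertain.

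**Figure D5:**
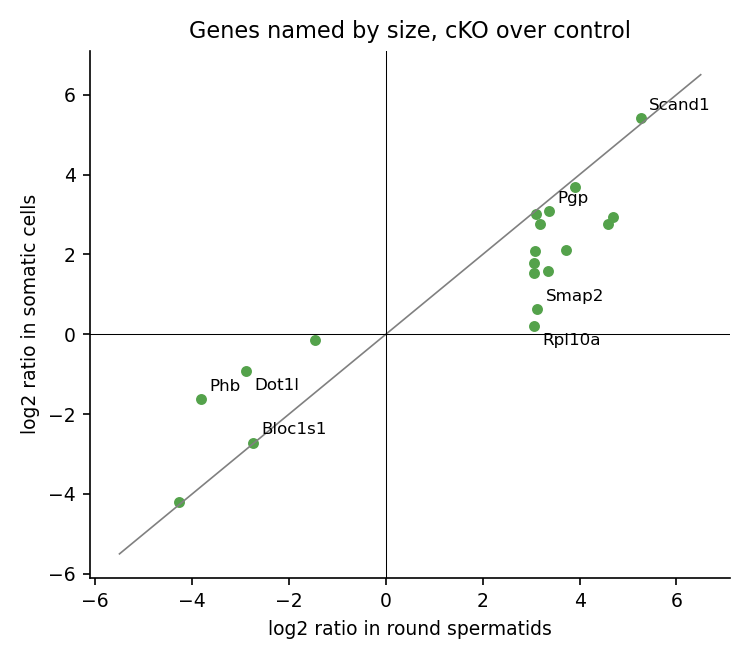
Log2 ratio in somatic cells against that in round spermatid-like cells for the genes named by size in round spermatid-like cells and measured in both, with the line of equal ratios. The 14 higher and 5 lower genes all had the same sign in both.

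Elongating spermatids exchange histones for protamines, and this class addressed whether that program differed in the cKO library. Transition protein and protamine transcripts took a smaller part of the RNA of elongating spermatid-like cells in the cKO library. The median of all genes was higher. The joint list of testis histones and replacement variants, and that of dissociation stress genes, were above the level of other genes. Tnp1, Tnp2, Prm1 and Prm2 took 28.6% of control and 20.6% of cKO UMIs, and the median ratio over 11912 measured genes was 0.42, or 0.21 when the 50 most abundant genes were left out of the totals.

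The transition protein and protamine list had a median of −0.36 in elongating spermatid-like cells, or −0.79 relative to the class median, at percentile 0.025. Prm1 was at −0.79 with 107444 CPM in the control and 62184 CPM in the cKO library. The ratios of Tnp1, Tnp2, Prm2 and Prm3 were −0.61, −0.36, −0.21 and −0.51. The list's somatic median was −0.97, and with the somatic ratios subtracted the list turned to 0.57. Testis histones and replacement variants had a median of 0.63 (−0.015 to 0.79), at percentile 98.65. In this list 6 of 11 genes were over 1.5-fold higher, and the somatic median was 0.30. Under median-of-ratios scaling the list median was 0.20. The histone variants H3f3a (0.73), H3f3b (0.75) and H2afv (1.23) were in that list. Hist2h2aa1 and H2al1a, which are not in it and have mostly shared 3′ ends, were among the lowest genes named by size. Dissociation stress genes had a median of 1.02, at percentile 99.6, with a somatic median of 0.66 and 5 of 7 genes over 1.5-fold higher. The upper quartile of all measured genes in this class was 0.78, itself past 1.5-fold. Neither count over 1.5-fold alone thus sets its list apart. Hspb1 was at 2.86, or −0.011 with the somatic ratio subtracted, and Jund was at 1.19. The remaining 15 lists lay inside the central 95%. Among their members, Gmcl1 was at 2.34, Papolb at 1.71, Zpbp at 1.93 and Hook1 (manchette) at 0.92. Chd5 was at 1.82 on 869 and 2442 UMIs with 0.99 in somatic cells, and Crebbp at 1.36. Sly was at −1.04 and Slxl1 at 1.17, and their 3′ ends are shared by 100% and 88.9%.

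The 10 highest genes named by size in elongating spermatid-like cells included Rabgef1 (5.36), Scand1 (5.03), Smap2 (3.85), March5 (3.75) and Apopt1 (3.72). March5 was at 1.04 and Apopt1 at 0.53 in somatic cells. Of these 10 genes, 9 were measured in somatic cells, all 9 with the same sign and 8 over 1.5-fold. The lowest included Hist2h2aa1 (−6.09), H2al1a (−5.38), Zfp367 (−2.39) and Ppp4r2 (−2.10, with −0.33 in somatic cells). Rpl35 was at −1.37, with −1.29 in somatic cells and 95% of its 3′ end shared.

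Mid to late spermatocytes addressed whether meiotic genes differed before the spermatid stages. Meiotic gene lists differed little between the libraries in this class. Flagellum genes were slightly lower and stress genes higher in the cKO library. The median over 16848 measured genes was 0.07. Flagellum and axoneme genes had a median of −0.13, at percentile 0.03, with 33 of 38 genes below 0 and none over 1.5-fold, and Tekt4 (−0.38) and Catsper1 (−0.39) among the lowest. Their somatic median was 0.24. Synaptonemal complex and recombination genes had a median of 0.17, at percentile 99.175, with Tex12 at 0.52 and Syce3 at −0.53. That median turned to −0.01 when clusters were given the same weights. X and Y multicopy and Y-linked genes had a median of −0.12, at percentile 1.99, with Zfy1 at −1.23 and Uty at −1.12. It turned to 0.04 with the same cluster weights and to 0.11 with called doublets kept. Stress genes had a median of 0.71, at percentile 99.97, with Jun at 1.28 and Junb at 1.16 and an equal somatic median of 0.71. It was 0.02 with a minimum of 200 UMIs per gene. The transition protein and protamine list was at −0.62, with a somatic median of −0.97. It was −0.07 with called doublets kept.

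The largest ratio of any gene named by size in mid to late spermatocyte-like cells was that of Hal, with 6 control and 1501 cKO UMIs and a log2 ratio of 8.0. Scand1 (5.50), Rabgef1 (4.39) and Pgp (3.30) were higher, as in round spermatid-like cells. Of the 10 highest genes 8 were measured in somatic cells, all 8 over 1.5-fold with the same sign. The lowest included Hist2h2aa1 (−5.49), Dynlt1b (−2.83), Bloc1s1 (−2.77) and Wdfy1 (−2.15, with −1.07 in somatic cells). Eno1 was at −1.38, with −1.64 in somatic cells and 87.0% of its 3′ end shared. Ddx4 was at −0.66, and Bcorl1 at −2.30 on 136 and 27 UMIs.

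Spermatogonium-like and early spermatocyte-like cells addressed the earliest germ cell stages compared here. Some gene lists differed between the libraries in these classes. The median ratio of all genes was −0.00 over 10072 genes in spermatogonium-like and 0.02 over 9561 genes in early spermatocyte-like cells. Free RNA was estimated at 15.6% of control and 22.3% of cKO UMIs in spermatogonium-like cells, and at 24.2% and 29.6% in early spermatocyte-like cells. The transition protein and protamine list was at −0.84 and −0.98 in these classes, both at percentile 0. For Tnp1, Tnp2, Prm1 and Prm2 together, the free RNA estimate came to 78.6% of the control and 159% of the cKO UMIs in spermatogonium-like cells, and to 126% and 234% in early spermatocyte-like cells. With called doublets kept the list median was −0.42 in spermatogonium-like cells and turned to 0.03 in early spermatocyte-like cells. In spermatogonium-like cells 4 other spermatid lists were higher, with medians of 0.32 for the manchette, 0.23 for the acrosome, 0.19 for the flagellum and 0.17 for RNA storage, at percentiles 99.97, 99.71, 99.485 and 99.42. After free RNA was subtracted, the manchette, flagellum and RNA storage medians turned to −0.09, −0.28 and −0.03. Subtraction of the somatic ratio, chosen after the data were seen, turned the acrosome and flagellum medians to −0.022 and −0.020. Glycolysis genes had a median of −0.17, at percentile 2.21. Testis histones had a median of −0.23, at percentile 0.34, in early spermatocyte-like cells, which turned to 0.18 with called doublets kept. The spermatogonial stem cell list was at −0.15 in spermatogonium-like cells, inside the central 95%. Ddx4 was at −0.97 in spermatogonium-like and −0.72 in early spermatocyte-like cells, with −0.41 in somatic cells. Scand1 was at 4.82 and 4.80, and Pgp at 3.32 in spermatogonium-like cells. H2afj was at 2.02 in both spermatogonium-like and somatic cells. Kpna2 was at −1.47 in early spermatocyte-like cells, with 98.3% of its 3′ end shared.

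Somatic cells gave a comparison in cells that the Cre does not target, although by the labels those of the cKO carry 1 delta allele. Most genes named by size in germ cells and measured in somatic cells differed between the libraries there too. Over all classes 52 genes were named by size, 24 higher and 28 lower in the cKO library. In somatic cells 31 of them were measured, all 31 had the same sign and 27 were over 1.5-fold. By cluster, 15 of 15 measured genes had the same sign in macrophage-like cells, 9 of 9 in mesenchymal-like cells and 18 of 19 in Leydig-like cells. Free germ cell RNA was estimated at 39.4% of control and 37.7% of cKO UMIs in somatic cells. Across all genes measured in both, the ratios in somatic cells and in a germ cell class had a correlation of 0.48, 0.48, 0.42, 0.39 and 0.44 from spermatogonium-like to elongating spermatid-like cells. These are across genes, which are not independent replicates.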

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

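All tests of the epididymal genes and of the genes named by size were chosen only after the result was seen, as were those of free RNA, short transcripts and libraries per genotype for the protamine genes. The stage make-up test of the protamine genes was written before its result. The epididymal genes drew attention because cells used in no comparison held a signal far above the control library.

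Epididymal genes appeared in the unnamed cells of the cKO library, at 236 CPM (225 to 247) or 1894 of 8036894 UMIs, against 4.47 CPM or 24 of 5375110 UMIs in the control library. Gpx5 had 943 UMIs there and 1 in the control, Spag11b 487 and 0, and Lcn5 389 and 0. Of the 10 listed genes 4 had over 10 UMIs in the cKO library and 10 or more times the control UMIs, so cells or RNA of the epididymis in the cKO library may be the source. In cluster 5, 1844 of the 1854 listed UMIs sat in 1 of 998 cKO barcodes, so this is close to a single cell. Rnase10, a listed gene that the testis also expresses, had 707 and 726 UMIs in all cells, and no biological explanation was tested.

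Genes named by size differed between the libraries in somatic cells too, which the germ cell Cre does not target but which by the labels carry 1 delta allele in the cKO. The somatic median ratio was 1.80 (1.11 to 2.76) when signed as in germ cells, for the 31 genes measured there. Genes of like length and GC had a median of 0.054 against 3.17 for the named genes. Transcript length and GC content thus did not shift such genes as a group. The named genes were picked for extreme ratios, so a wide gap was likely in advance and decides nothing more. Shared 3′ ends are a candidate explanation for the lower genes, since 53.6% of these (15 of 28) share over 50% of their 3′ end against 3.91% of 19246 measured genes, but only 4.17% of the higher genes (1 of 24) do. Free germ cell RNA in somatic cells stays open, with a median somatic level of 72.7% (51.2 to 97.4) of the all-cell level against a free RNA share of 39.4%, and a median of 1.63 (0.33 to 2.71) over 9 genes whose somatic level exceeded the all-cell level. Since free RNA would carry a germ cell difference into somatic cells, loss of DOT1L in germ cells alone stays open too. A batch, strain or counting difference between the libraries cannot be told apart from genotype with 1 library per genotype, and an effect of the delta allele in somatic cells was not tested.

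Transition protein and protamine genes were lower in the cKO library in every class, somatic cells included, but with called doublets kept the list median was 0.025 in early spermatocyte-like and −0.07 in mid to late spermatocyte-like cells. A different mix of the control stages in elongating spermatid-like cells is argued against. After matching to control stages the median of Tnp1, Tnp2, Prm1 and Prm2 was −0.49, or −0.85 relative to the class median. Each cKO cell took the nearest control stage whatever its fit, so stages that the control clusters do not hold or resolve stay open. Free RNA may supply these transcripts in spermatogonium-like, early spermatocyte-like and mid to late spermatocyte-like cells. The estimate came to 78.6% and 159%, 126% and 234%, and 121% and 170% of their control and cKO UMIs. Where it exceeds the observed UMIs the estimate is too high, so it cannot size that part. In round and elongating spermatid-like cells the estimate came to 23.1% or less. Lower recovery of short transcripts stays open for part of the difference, since genes of up to 674 nucleotides lay −0.20 from the class median against −0.91 for the 4 genes in elongating spermatid-like cells. With 1 library per genotype a batch, strain or counting difference stays open, and so does a lower level in the spermatids themselves, which would also lower the free RNA.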

How the results depend on the processing

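Low-RNA clusters put into their classes, spermatids matched to control stages and subtraction of the somatic ratio were chosen after seeing the data, and the other settings were planned. Over 1984 values of 211 results, 1849 kept their sign, 55 reversed, 427 moved beyond the interval of the main value and 1502 stayed inside it. That interval covers counting error for shares and genes. For list medians and depth it comes from order-statistic intervals of medians over genes or cells. Of the 135 that changed sign, those called reversed had a main interval that excluded 0 or a list median outside the central 95% of random lists. For shares 38 of 40 kept their sign, for genes 1063 of 1091, for list medians 730 of 833 and for depth 18 of 20. No paired analysis was possible because each genotype has 1 library, both numbered replicate 1, and no test was made. Lists were not planned under own CPM, thinned cells or the stricter filter.

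Shares moved as follows. With 1000 UMIs and 500 genes they were 0.41 for early spermatocyte-like, −0.19 for mid to late spermatocyte-like and −0.49 for elongating spermatid-like cells. Among germ cells only they were 0.88, 0.11 and −0.17 for these classes and −0.22 for round spermatid-like cells. By highest marker score they were 0.30 for spermatogonium-like, 0.28 for early spermatocyte-like, −0.14 for round and −0.49 for elongating spermatid-like cells. The early spermatocyte-like share was 0.47 at resolution 0.5, the mid to late spermatocyte-like share 0.022 with doublets kept, and the round spermatid-like share −0.14 with low-RNA clusters in their class. The elongating spermatid-like share was −0.43 at resolution 2.0 and −0.48 with every barcode. The germ cell denominator leaves out low-RNA and unnamed cells, and the cause of the other moves was not tested.

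The ratio of Dot1l in mid to late spermatocyte-like cells was −1.28 as the mean of own CPM, −1.11 by median of ratios, −1.15 with the stricter filter and −0.13 with the somatic ratio subtracted. In round spermatid-like cells it was −2.55 in thinned cells, −3.35 with free RNA subtracted, −2.64 with low-RNA clusters in their class and −1.97 with the somatic ratio subtracted. The cause was not tested. The somatic Dot1l ratio may hold an effect of the delta allele, which its subtraction would remove.

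With the somatic ratio subtracted, most reversals arose by construction, since the ratio in somatic cells was as large or larger. Somatic cells hold free RNA of spermatids, so this setting subtracts part of the same source. The somatic pools of the 2 libraries also differed in cell mix. The transition protein and protamine list reversed to 0.019 in spermatogonium-like, 0.31 in mid to late spermatocyte-like, 0.31 in round and 0.57 in elongating spermatid-like cells. In round spermatid-like cells Tnp1 was 0.14, Tnp2 0.34, Prm1 0.35, Prm2 0.24, Prm3 0.41, Scand1 −0.15, H2afx −1.61, Zpbp −0.86, Eno1 0.37 and Hspb1 −1.63. In elongating spermatid-like cells Tnp1 was 0.43, Tnp2 0.60, Prm1 0.71, Prm2 0.63, Prm3 0.57, Dot1l 0.022, Scand1 −0.38, Zpbp −0.30, Eno1 0.44 and Hspb1 −0.011. In mid to late spermatocyte-like cells Prm1 was 0.31 and Eno1 0.26. In spermatogonium-like cells Dot1l was 0.10, Scand1 −0.59 and Bloc1s1 0.054, and in early spermatocyte-like cells Dot1l was 0.49 and Scand1 −0.60. Among lists, acrosome and flagellum medians in spermatogonium-like cells reversed to −0.022 and −0.020. In mid to late spermatocyte-like cells histone removal was −0.017, RNA storage −0.072 and the synaptonemal complex −0.011. In round spermatid-like cells histone removal was −0.011, the manchette −0.0044, X and Y multicopy genes 0.0085 and stress genes −0.20.

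For free RNA, doublets and cluster weights the cause of the reversals was not tested. With free RNA subtracted, spermatogonium-like medians were −0.029 for RNA storage, −0.086 for the manchette and −0.28 for the flagellum, and the elongating spermatid-like synaptonemal median was −0.20. With doublets kept, early spermatocyte-like medians were 0.025 for transition proteins and protamines, 0.18 for testis histones and −0.016 for stem cell genes, and the mid to late spermatocyte-like X and Y median was 0.11. With the same cluster weights the stem cell median was −0.0056 in early spermatocyte-like cells, and in mid to late spermatocyte-like cells the synaptonemal median was −0.0093 and the X and Y median 0.044. Slc2a3 in round spermatid-like cells was 0.31 there, where only cluster 10 holds enough cells of both libraries (clusters 3, 6 and 14 in elongating spermatid-like cells). Median-of-ratios scaling subtracts the class median from every gene alike, so by construction any list median between 0 and the class median changes sign under it. Among these, RNA storage was −0.036 and meiotic divisions −0.027 in round and the flagellum −0.16 in elongating spermatid-like cells.

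Counting depth limits some values. Dot1l in elongating spermatid-like cells rests on 70 and 30 UMIs and in somatic cells on 17 and 37, and the simulated-doublet thresholds caught 17.2% and 22.5% of simulated doublets.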

Other observations

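The separation of the libraries was tested by dropping library-wide genes and by thinning, both written before their results, while the test of sex chromosome genes and the count of libraries per genotype were chosen only after the result was seen. The libraries lay furthest apart in the spermatid classes, and no histone mark was measured. In round spermatid-like cells the share of nearest neighbours from the other library was 11.2% of that in a full mixture, and in elongating spermatid-like cells 16.9%. In mid to late spermatocyte-like cells it was 65.5%, in spermatogonium-like cells 82.6% and in early spermatocyte-like cells 88.0%.

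Without genes that also differed in somatic cells or spermatogonium-like cells (1594 of 2000 genes left) the share was 22.8% in round and 43.6% in elongating spermatid-like cells. With every cell thinned to 2000 UMIs it was 59.2% and 39.8%. Thinning also raised the share from 65.5% to 87.3% in mid to late spermatocyte-like cells and from 82.6% to 91.5% in spermatogonium-like cells. It therefore raises mixing in other classes too, and its result does not decide for or against depth. Library-wide genes, depth, and a batch, strain or counting difference all stay open with 1 library per genotype.

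A hypothesis was that X-linked expression returned more weakly after meiosis in the cKO library. Round spermatid-like cells had 450 measured X-linked genes with a median ratio of −0.05, at percentile 0 among expression-matched random lists, whose central 95% ran from 0.10 to 0.21. The percentile was also 0 with spermatids matched to control stages (−0.05) and with the same cluster weights (−0.36). In mid to late spermatocyte-like cells 381 X-linked genes were at −0.11, also at percentile 0, and in early spermatocyte-like cells at 0.12, at percentile 100. In somatic cells they were at −0.01, at percentile 2.35, and in elongating spermatid-like cells inside the central 95%, at percentile 18.9. Some autosomes lay outside the central 95% too, but by less. Relative to the class median the X was at −0.17 in round spermatid-like and −0.18 in mid to late spermatocyte-like cells, the lowest of 20 chromosomes in both, while the furthest autosomes were at 0.04 (chromosome 2) and −0.04 (chromosome 14). The percentile of 0 in round spermatid-like cells is the observation that raised the hypothesis, so it does not support it. X-linked genes were also below their random lists in mid to late spermatocyte-like and somatic cells, so a weaker return after meiosis stays open, without a replicate.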
